A study of Danio rerio with 2 samples.

How the data were processed

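The data are droplet libraries of female zebrafish pituitary, 1 from WT fish and 1 from amh knockout fish, grouped by the genotype in the labels. Glands were dissociated with trypsin and collagenase and libraries were made with the 10x Chromium 3' kit, version 3.1, per the labels' protocols. The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 5.0.1 on build GRCz11 per the submitters' processing notes and the file headers; the annotation version is not given in the sources used here. The barcode and feature files hold other text only, the barcodes of the authors' cell calling and the deposited gene names. The design text also names chromatin profiling and a bmpr2a knockout, which are not analysed here, and the labels give no time of day. No genome was used; genes carry the symbols of the deposited feature table, and each gene named in the text stood for 1 gene identifier there. In all, 11 names of the gene lists matched no symbol.

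Cells were kept with at least 200 detected genes and a mitochondrial share of at most 20%. In WT 83 and in the amh knockout 232 barcodes had fewer genes, and 320 and 282 had a higher mitochondrial share. Scrublet, run per library at an expected rate of 6%, called 0 doublets in both, so no doublets were removed. It may not have worked, and whether doublets were removed before deposit is not given in the sources used here. Removing the top 5% of cells by UMIs was added as an alternative. Kept cells held 47150367 UMIs in WT and 48256645 in the amh knockout.

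Both libraries were clustered together with scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and Leiden ran at resolution 1 on a graph of 15 neighbours. The graph weighted shared neighbours, with links of an overlap over 1/15; it replaced, after the data had been seen, scanpy's own graph, which was kept as an alternative. This gave 24 clusters, and clusters under 20 cells would have been left out. Markers of 19 cell types were fixed before the data were examined. The naming rule was set after the data had been seen. A name needed at least 3 markers detected in at least 5% of the cluster's cells and 2 of them over 2-fold. A cluster with no such name was called by its leading hormone gene when it had at least 100 cells, that gene passed 150000 CPM, no other hormone passed 100000 CPM, and its median depth was at least 0.5 of the library median. Gonadotroph-like clusters were split by their leading gene, fshb or lhb. Clusters 2, 14, 16 and 23 stayed unnamed, with shares given in the report. The names gh1-led and prl-led mark clusters that rest on a hormone gene rather than 3 markers. Cluster 12 of the corticotroph-like class had gh1 as its most abundant hormone RNA. In cluster 0 of the gh1-led class plp1b, a myelin gene, was among the 10 leading genes.

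Raw UMIs were summed per library over all kept cells and per class, for classes with at least 100 kept cells in both libraries. CPM, the UMI counts scaled to the total of the same cells, their ratio (amh knockout over WT) and its exact conditional binomial (Clopper-Pearson) 95% interval were computed from the deposited counts; 0.5 UMIs were added to both sums for log2 ratios, and each log2 ratio was set relative to the median gene. Shares of cells have exact Clopper-Pearson intervals. No p-value, standard error or count of changed genes was computed, since cells are not replicates. Values that rest on under 200 UMIs have wide intervals. Shares of cells with a UMI were also computed after thinning every cell to 1000 UMIs, with 2000 and no thinning as alternatives.

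There were 22 gene lists, fixed before the data were examined: clock, its positive limb, its E-box outputs and negative limb, light-induced and D-box genes, the Amh and BMP pathway, BMP-SMAD targets, hormones, pituitary transcription factors and receptors, activin with inhibin and follistatin, hormone processing and secretion, endoplasmic reticulum stress and protein folding, immediate early and dissociation, heat shock, glucocorticoid-responsive, mitochondrially encoded, nuclear oxidative phosphorylation, cell cycle, cholesterol synthesis, interferon response, antigen presentation and macrophage, red blood cell, and GABA with melatonin signalling. Some genes are in more than 1 list. Members with at least 30 UMIs counted as measured. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

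The rule for named genes was fixed before the data were examined. It took any measured member of the clock, Amh and BMP, and hormone lists, up to 4 members of other lists with the largest absolute ratio, and the 12 highest and 12 lowest library-wide ratios among genes with at least 200 UMIs and a UMI in at least 2% of 1 library's cells. Within a class it took the 6 highest and 6 lowest ratios among genes with at least 100 UMIs and a UMI in at least 10% of its cells in 1 library, without the cell type markers. Loci with clone names were counted and not named. Genes named as leading a cluster describe the cluster only.

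The ratio and list steps were tested on counts simulated for the library-wide comparison from the average profile of both libraries, with 200 genes changed among 11944 for the ratio step and 17427 genes in the list step. The intervals held the true ratio for 96% of genes raised 2-fold, 90% of those raised 4-fold, 96% of those at 0.5 and 96% of those at 0.25 of the WT level, and for 95.5% of 11744 unchanged genes. A simulated list of 15 genes made 4-fold lower had a median of -1.92, and a list of 15 unchanged genes had -0.01 (percentile 35.6). The simulated counts were Poisson draws, the counting error that the intervals assume. They check the computation only and hold no variation between libraries beyond counting.

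Alternatives fixed before the data were examined were all barcodes, a stricter cell filter (at least 500 genes, at most 10% mitochondrial), doublets kept, resolutions 0.5 and 2, each library clustered alone, hormone genes left out of the clustering, endocrine classes from each cell's leading hormone, CPM without hormones, median-of-ratios scaling, the mean of per-cell CPM, a minimum of 10 UMIs, list medians without members at or under 3 UMIs in 1 library, and class-standardised sums with the same class weights in both libraries. The class-standardised sums left out groups with under 10 cells in either library. Added after the data had been seen were the top 5% of cells by UMIs removed, scanpy's own neighbour graph, and kept cells without erythrocyte-like cells.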

Results

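Single-cell RNA was measured in dissociated pituitary glands of female zebrafish with droplet libraries that read the 3' ends of transcripts. There were 2 libraries, 1 from wild-type (WT) fish and 1 from amh knockout fish. The series title and design text place them in a study of how anti-Müllerian hormone (Amh) signalling maintains circadian rhythms. The WT library held 5900 barcodes with 47511778 unique molecular identifiers (UMIs), and the amh knockout library held 5174 barcodes with 48601090 UMIs. The cell filter kept 5549 WT cells (94.1%) and 4754 amh knockout cells (91.9%), with median depths of 5392 and 4536.5 UMIs and medians of 1542 and 1189.5 detected genes per cell. The median mitochondrial share was 3.40% in WT and 3.37% in the amh knockout. With 1 library per genotype there was no replicate and no test, and every difference below compares these libraries rather than the genotypes. All intervals are exact 95% intervals that cover counting error only. Growth hormone RNA took 9.77% of kept UMIs in WT and 29.4% in the amh knockout, and the median log2 ratio (amh knockout over WT) of 17422 genes on the CPM scale (UMI counts scaled to the library total) was -0.83. With hormone genes left out of the totals that median was -0.45, so hormone RNA does not account for the whole shift. Log2 ratios are therefore given relative to the median gene of the same cells, library-wide or within a class. Any library-wide value between 0 and 0.83 on that scale lies below 0 on the CPM scale. Within the 9 classes compared the median gene lay between -1.32 (gh1-led) and -0.17 (lhb-led) on the CPM scale, so small values above 0 can turn there too.

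The amh transcript itself was almost undetected in the pituitary, with 13 UMIs in WT and 8 in the amh knockout, so its ratio was not measurable at this depth (relative log2 ratio 0.13, interval -1.38 to 1.48). A 3' tag outside the mutated part also checks nothing about the genotype. The type II receptor genes bmpr2a and bmpr2b of the bone morphogenetic protein (BMP) family were lower in the amh knockout library: bmpr2a at -0.75 (interval -0.90 to -0.61; 1461 against 497 UMIs) and bmpr2b at -0.66 (-0.87 to -0.46). The type II receptor gene acvr2aa lay at -0.02 (-0.16 to 0.13; 1041 against 591 UMIs), and acvr2ab, acvr2ba and acvr2bb, with fewer UMIs, between -1.27 and -0.97. Of the receptor-regulated Smad genes, smad9 was lower, at -1.39 (-1.76 to -1.06), while smad1 was at 0.01 (-0.61 to 0.60) and smad5 at 0.67 (0.54 to 0.79), both below 0 on the CPM scale. With the same class weights in both libraries smad9 was at -0.71, smad1 at -0.82 and smad5 at 0.57, and bmpr2a and bmpr2b were at -0.62 and -0.58. Of the inhibitor-of-differentiation genes, which BMP signalling induces in many tissues, id1 was higher, at 2.16 (2.06 to 2.26, 1193 against 3057 UMIs). So were id3 at 1.48, id2b at 1.04 and id2a at 0.93, while id4, at 0.74, lay below 0 on the CPM scale. Of the 10 BMP-SMAD target genes measured, 8 lay above the median gene. Their median of 0.81 sat at percentile 99.9 of 10000 random lists matched on expression, and on the CPM scale it was -0.02. The matched range ended at 0.54. With the same class weights in both libraries id1, id2b, id4, id3 and bambia lay above 0.54, from 1.04 (id1) to 0.66 (bambia). Under it lay id2a at 0.34, bambib at 0.30, smad7 at 0.24, smad6a at 0.07 and smad6b at -0.48. With those weights the median of these genes thus lay between 0.34 and 0.66, and a place above the matched range is not shown. Of the 32 measured members of the wider Amh and BMP pathway list, 16 lay above and 16 below the median gene (median 0.00, percentile 62.5).

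The id1 difference was not spread evenly over the cells. In folliculostellate or progenitor-like cells, which held most id1 UMIs, it was 0.78 (0.68 to 0.89; 932 against 2632 UMIs), or 0.26 on the CPM scale. The share of these cells with an id1 UMI was 39.4% in WT and 39.0% in the amh knockout after thinning to 1000 UMIs per cell, and 55.7% and 51.5% unthinned. In corticotroph-like cells it was 3.30 (2.51 to 4.31) on 13 against 102 UMIs, beside antigen presentation and macrophage genes at a median of 1.71 in the same cells (percentile 100; 9 of 11 above the median gene). In lhb-led gonadotroph-like cells it was -0.17 (-0.83 to 0.45). With the same class weights in both libraries, the library-wide values were 1.04 for id1, 0.71 for id3, 0.34 for id2a and 0.94 for id2b, beside a ratio of shares of folliculostellate or progenitor-like cells of 2.72. The BMP-SMAD target median was above 0 in 8 of 8 classes, and above the central 95% of its matched lists in 3 of them. On the CPM scale it turned to -1.22 in gh1-led, -0.33 in folliculostellate or progenitor-like and -0.06 in prl-led cells. The bmpr2a value ranged from -1.50 in folliculostellate or progenitor-like cells to 0.06 in prl-led cells over the 7 classes that measured it.

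Gonadotroph-like cells led by fshb, the beta subunit gene of follicle-stimulating hormone, were abundant in WT and rare in the amh knockout. They made up 11.4% of kept WT cells (634 cells, interval 10.6% to 12.3%) and 1.01% of amh knockout cells (48 cells, 0.745% to 1.34%), a ratio of 0.0884 (0.0645 to 0.119). Clustering without the hormone genes gave 606 and 53 cells and a ratio of 0.102 (0.0756 to 0.135). The name still came from fshb, so these cells are counted by that gene in both settings. When each library was clustered alone the ratio was 0.390, with the name shared by 80 amh knockout cells led by fshb and 120 led by soul5. Gonadotroph-like cells led by lhb, the luteinising hormone beta subunit gene, were at 10.4% in WT and 14.7% in the amh knockout (ratio 1.42, 1.27 to 1.58). That direction turned when each endocrine cell was assigned by its leading hormone gene (ratio 0.784). The lhb-led cells also came from a different cluster in each library: cluster 3 held 566 WT and 76 amh knockout cells, and cluster 4 held 11 and 624.

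Among the other endocrine cells, gh1-led cells, which carry growth hormone RNA, made up 13.5% of WT and 20.6% of amh knockout cells (ratio 1.52, 1.39 to 1.68). Corticotroph-like cells were at 10.7% and 14.998% (1.40, 1.25 to 1.56), and somatolactotroph-like cells at 4.11% and 5.05% (1.23, 1.02 to 1.48; 2.00 with classes from the leading hormone). For thyrotroph-like cells the shares were 4.00% and 3.91% (0.978, 0.8005 to 1.19), and for prl-led cells, which carry prolactin RNA, 5.03% and 5.57% (1.11, 0.934 to 1.32). Melanotroph-like cells were at 1.53% and 0.926% (0.604, 0.410 to 0.879), a ratio of 0.337 when clustered without hormone genes and 0.221 with all barcodes. Without the hormone genes in the clustering the ratios were 1.57 for gh1-led, 1.45 for corticotroph-like and 1.39 for lhb-led cells. Shares are parts of a whole, so fewer fshb-led and erythrocyte-like cells raise the shares of the other classes. With erythrocyte-like cells left out the ratios were 1.22 for corticotroph-like, 1.23 for lhb-led and 0.850 for thyrotroph-like cells. The corticotroph-like class joined cluster 6 (62 WT and 487 amh knockout cells), cluster 11 (387 and 10) and the shallow cluster 12 (145 and 216), and the gh1-led class joined cluster 0 (666 and 434), cluster 9 (72 and 392) and cluster 19 (13 and 155).

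Erythrocyte-like cells, marked by haemoglobin genes, also had a large gap: 15.4% of WT and 2.71% of amh knockout cells (ratio 0.176, 0.145 to 0.212). This ratio turned to 3.79 under the stricter cell filter and to 3.33 when each library was clustered alone, where an amh knockout cluster with gh1 and pomca RNA also took the name, and it was 0.328 with all barcodes. Folliculostellate or progenitor-like cells were at 2.52% and 6.86% (2.72, 2.22 to 3.34; 1.62 under the stricter cell filter and 4.97 with each library clustered alone), and T or NK cell-like cells at 1.78% and 4.16% (2.33, 1.82 to 3.002). Macrophage or microglia-like cells were at 4.99% and 3.68% (0.737, 0.607 to 0.894), a ratio that turned to 1.04 when each library was clustered alone. Clusters left unnamed held 6.04% of WT and 12.9% of amh knockout cells (cluster 2, shallow cells rich in tshba and mitochondrial RNA), 4.51% and 0.421% (cluster 16, shallow), 3.53% and 2.40% (cluster 14, led by soul5, hebp2 and prdx1), and 0.469% and 0.0210% (cluster 23, led by stmn1a, mki67 and top2a).

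**Figure D1:**
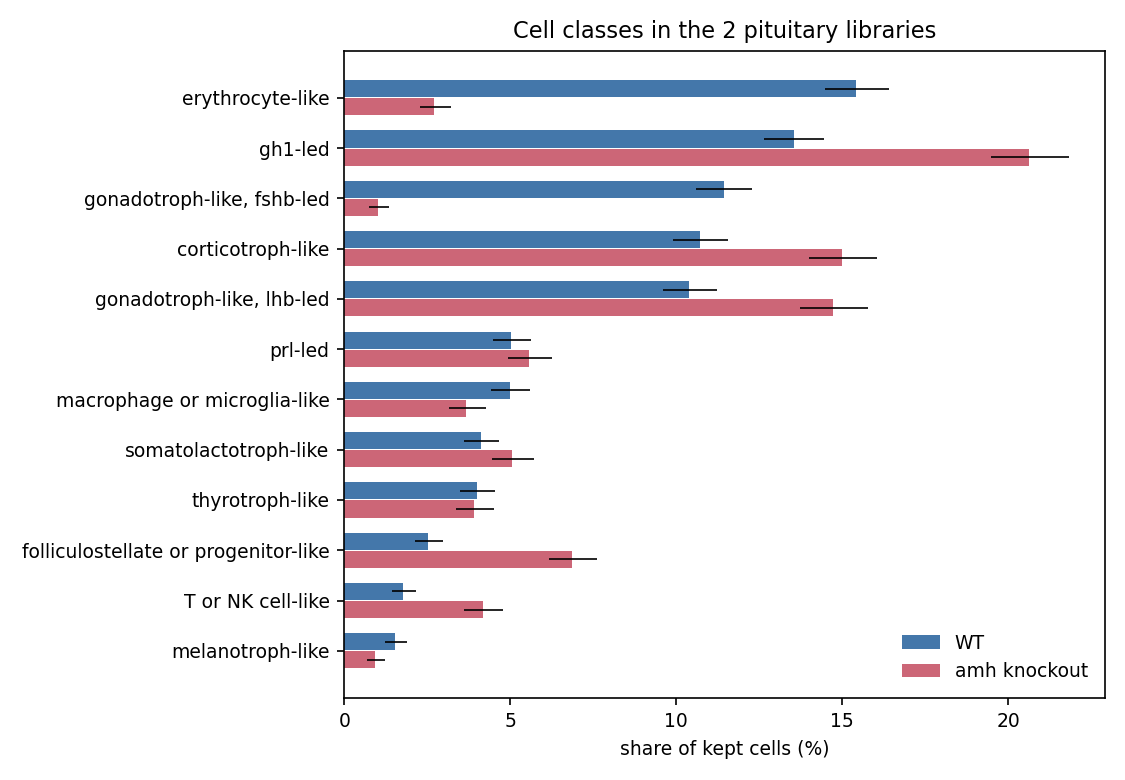
Share of kept cells (%) in each cell class of the WT library (blue) and the amh knockout library (red), 1 library each, with exact 95% binomial intervals for counting error. Gonadotroph-like, fshb-led cells stood at 11.4% in WT and 1.01% in the amh knockout.

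Of the hormone genes, fshb was lower and gh1, smtlb, prl and tshba were higher in the amh knockout library. The fshb transcript had 223248 UMIs in WT and 14444 in the amh knockout (relative log2 ratio -3.15, -3.17 to -3.12). It was below the median gene in 9 of 9 classes, which include classes that should lack it. In lhb-led cells it stood at 338 CPM in WT and 113 CPM in the amh knockout, with a UMI in 54.8% and 15.9% of cells at median depths of 17473 and 11266.5 UMIs. In gh1-led cells, which should lack fshb, the shares were 37.0% and 3.57% at median depths of 7590 and 9166 UMIs, so background fshb RNA differed between the libraries. Within fshb-led cells, which were named by this gene, it stood at 27791 CPM and 25992 CPM, and with the same class weights in both libraries, which rest on that class too, the value turned to 0.37. Growth hormone, gh1, was at 2.42, and somatolactin beta, smtlb, at 2.99 (160456 against 731567 UMIs). Prolactin, prl, was at 1.31 and the thyrotropin beta subunit, tshba, at 1.17. Values between 0 and 0.83, which turn on the CPM scale, were seen for pomca (0.75), smtla (0.69), lhb (0.19) and the common alpha subunit cga (0.02). Of the 9 hormone genes measured, 8 lay above the median gene (median 0.75, percentile 95.3; -0.09 on the CPM scale). Within somatolactotroph-like cells smtlb was at 58910 CPM in WT and 254348 CPM in the amh knockout.

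Hormone RNA in cells of other classes differed between the libraries as well, in some classes against the library-wide direction. On the CPM scale the log2 ratio of gh1 was -0.63 in prl-led and -0.42 in thyrotroph-like cells, that of prl was -2.05 in melanotroph-like and -0.71 in fshb-led cells, and that of fshb was 1.55 in T or NK cell-like cells (43 against 223 UMIs), although the share of those cells with an fshb UMI was 34.3% in WT and 13.1% in the amh knockout. A gh1 UMI was present in 97.47% of WT and 100% of amh knockout macrophage or microglia-like cells, whose median depths were 1615 and 1874 UMIs, and gh1 there stood at 2885 and 122967 CPM. In erythrocyte-like cells gh1 stood at 3807 and 10445 CPM. Pituitary transcription factors and receptors had a median of 1.34 in the macrophage or microglia-like cells (percentile 100; 12 of 14 above the median gene), and hormone processing and secretion genes 1.09 (percentile 100; 12 of 12 above). No doublets were removed, so their gh1 RNA was not separated into free RNA and doublets. In those cells smtlb had a UMI in 22.4% and 60.0%, and fshb in 31.8% and 2.86%.

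Most core clock genes of the negative limb and most genes induced by light were lower in the amh knockout library, while arntl1a, the gene of the clock activator Bmal1a, and the repressor gene nfil3-5 were higher. The period genes per3 (-2.53, -2.65 to -2.41; 6042 against 601 UMIs), per1a (-2.11, -2.36 to -1.88), per2 (-1.96, -2.05 to -1.88; 8677 against 1279 UMIs) and per1b (-1.21) were all lower. So were the cryptochrome genes cry1b (-1.54) and cry2 (-1.19), the Rev-erb genes nr1d1 (-1.15) and nr1d2b (-1.23), and the clock-controlled transcription factor genes dbpa (-1.71), tefa (-1.63), ciartb (-1.70) and ciarta (-1.46). In the opposite direction stood nfil3-5 (2.71, 2.57 to 2.84; 586 against 2195 UMIs), arntl1a (2.15, 1.92 to 2.38; 222 against 565 UMIs), cry4 (1.90), nfil3 (1.40), fbxl3a (1.18) and, on 28 against 35 UMIs, the Rev-erb gene nr1d4a (1.12). Other members of the same families lay between 0 and 0.83, where the direction turns on the CPM scale: cry3b at 0.67, nr1d2a at 0.22 and nr1d4b at 0.83. Among 15 E-box outputs and negative-limb genes, 11 lay below the median gene, with a median of -1.21 at percentile 0 of the matched lists, whose central 95% ran from -0.29 to 0.56.

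Light-induced and D-box genes gave a median of -1.45, also at percentile 0, with 10 of 11 below the median gene. They included cry5, a photolyase (-2.97, -3.29 to -2.67), the DNA repair gene xpc (-2.20) and lonrf1 (-2.09). The positive limb had no common direction: 6 of 10 genes lay below the median gene (median -0.10, percentile 36.2; -0.79 in prl-led cells, percentile 1.53), with npas2 at -1.62, clocka at -0.42 and arntl1b at -0.57 beside arntl1a. Over all 45 measured clock genes the median was -0.36 (percentile 0), with 29 below the median gene. After thinning to 1000 UMIs per cell, which left 4197 WT and 4059 amh knockout cells and left out 1352 and 695, per2 had a UMI in 15.8% and 3.30% of cells, per3 in 11.7% and 2.19%, tefa in 19.3% and 5.03%, and nfil3-5 in 1.48% and 3.79%. Unthinned, the shares were 47.6% and 17.3% for per2, 42.7% and 10.4% for per3, 51.4% and 23.8% for tefa, and 4.90% and 18.1% for nfil3-5. Thinning equalises depth, and the shares are not relative to the median gene. At 1000 UMIs the median number of detected genes was 461 in WT and 400 in amh knockout cells, and 458 and 246 in gh1-led cells.

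The lower clock outputs were seen in every class compared, endocrine and non-endocrine. Non-endocrine cells also held hormone RNA of other classes, and their clock UMIs were not separated from such background. The classes are therefore not independent of each other. The E-box median was below 0 in all 9 named classes with at least 100 cells in both libraries, from -1.80 in folliculostellate or progenitor-like and lhb-led cells to -0.71 in macrophage or microglia-like cells, with percentiles of at most 1.62. The gene per3 was below the median gene in 9 of 9 classes, at -3.17 (-3.49 to -2.88) in lhb-led, -3.48 (-4.80 to -2.56) in somatolactotroph-like, -2.56 in thyrotroph-like, -2.20 in gh1-led and -1.60 in corticotroph-like cells. The genes per2, tefa and nr1d2b were also below it in 9 of 9 classes. After thinning to 1000 UMIs, per2 had a UMI in 7.92% of WT and 7.79% of amh knockout prl-led cells. For tefa in somatolactotroph-like cells the thinned shares were 14.9% and 10.9%, with overlapping intervals. In the other named classes the thinned shares of both genes were also lower in the amh knockout library. In erythrocyte-like cells, with 0 of 58 amh knockout cells, the intervals overlapped for both genes. Light-induced and D-box medians were below 0 in all 9 classes, but within the central 95% of matched lists in macrophage or microglia-like (-0.71, percentile 5.48) and somatolactotroph-like cells (-0.37, percentile 10.8). In erythrocyte-like cells the E-box median rested on 6 genes and the light-induced median on 3, each with 1 gene lacking UMIs in 1 library. With that gene set at a bound of 3 UMIs, the light-induced median there was -1.09, inside the matched range (lower end -1.11). Of the higher genes, arntl1a was above the median gene in 6 of 6 classes that measured it, at 2.85 (2.15 to 3.72) in gh1-led and 1.92 (1.52 to 2.34) in lhb-led cells. Its lowest class value, 0.14, lay below 0 on the CPM scale. Its thinned share was 3.33% in WT and 2.87% in amh knockout prl-led cells. That share was also lower in macrophage or microglia-like and erythrocyte-like cells, on few cells with a UMI, and higher in the other named classes. The nfil3-5 value was 4.39 in gh1-led, 4.04 in thyrotroph-like and 3.65 in lhb-led cells, yet -0.65 (-0.96 to -0.34) in prl-led cells. The Rev-erb gene nr1d1 was at -2.65 in lhb-led and 0.81 (0.28 to 1.32) in somatolactotroph-like cells. In the unnamed cluster 14 the E-box median was -2.76 and in cluster 2 it was -0.93.

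**Figure D2:**
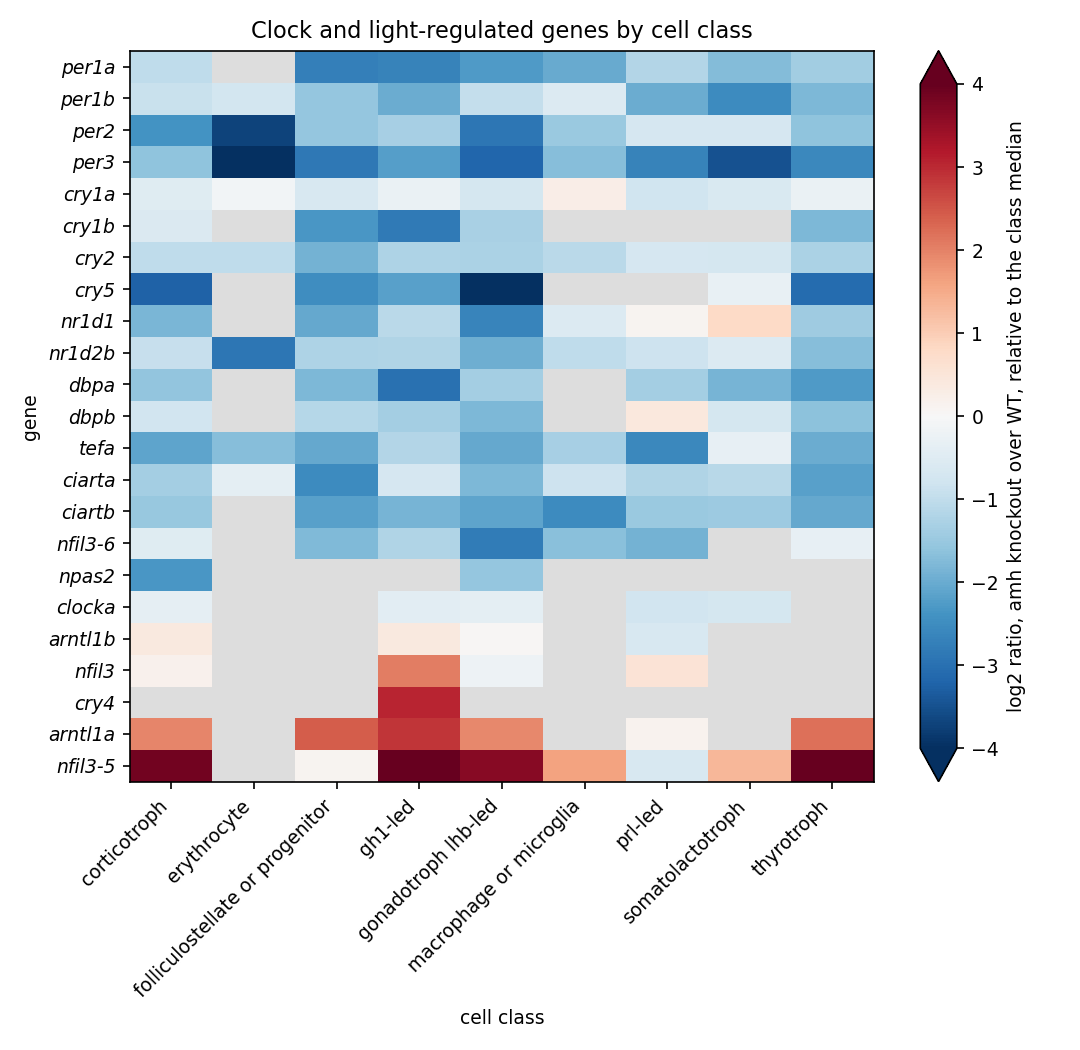
Log2 ratio (amh knockout over WT) of clock and light-regulated genes in 9 cell classes, relative to the median gene of each class; blue is lower and red higher in the amh knockout, grey was not measured, and colours stop at -4 and 4. The per3, per2, tefa and nr1d2b lines are blue in every class, and the arntl1a line is red in the 6 classes that measured it.

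Heat shock genes, which encode protein-folding chaperones, were lower in the amh knockout library. The median over 18 genes was -0.91 (percentile 0), with 15 below the median gene, among them hsp90aa1.2 (-1.50, -1.52 to -1.48; 124761 against 25384 UMIs), dnaja1 (-1.71) and dnajb1a (-1.41). Within classes the heat shock median ran from -2.13 in thyrotroph-like cells to -0.18 in somatolactotroph-like cells (percentile 6.39), and it was -1.93 in corticotroph-like cells. Immediate early genes, which respond quickly to handling, went the other way in several classes, with medians of 0.87 in corticotroph-like (percentile 100), 0.47 in lhb-led and thyrotroph-like and 0.38 in macrophage or microglia-like cells (percentiles of at least 99.8). They lay below the matched lists in gh1-led (0.02) and erythrocyte-like cells (-0.33), at percentiles of at most 0.280, and within their central 95% in folliculostellate or progenitor-like (0.04, percentile 3.76), prl-led and somatolactotroph-like cells. On the CPM scale the medians in macrophage or microglia-like (-0.02), gh1-led (-1.31), folliculostellate or progenitor-like (-0.49), prl-led (-0.08) and somatolactotroph-like cells (-0.41) lay below 0. The corticotroph-like cells also had the antigen presentation and macrophage median of 1.71, and a hormone gene median of 2.14 (percentile 100, 7 of 8 above the median gene). In them gh1 stood at 9626 CPM in WT and 62811 CPM in the amh knockout, and smtlb at 35 and 12451 CPM. Library-wide, 29 of 39 lay above the median gene (median 0.42, percentile 72.2; -0.41 on the CPM scale), with the cytokine-signalling suppressor socs3b at 2.51, cebpd at 1.90 and klf4 at -2.73.

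Nuclear genes of oxidative phosphorylation all lay above the median gene, 29 of 29, with a median of 0.67 (percentile 99.3), which turned to -0.17 on the CPM scale. The central 95% of matched lists ran from 0.09 to 0.62, so random lists of like expression mostly lay above the median gene too. Within classes the oxidative phosphorylation median was above 0 in 9 of 9, from 0.16 in macrophage or microglia-like to 0.90 in gh1-led cells. It was above the central 95% of matched lists in 6 of 9. It was within that range in macrophage or microglia-like (percentile 89.0), thyrotroph-like (91.0) and somatolactotroph-like cells (96.9). On the CPM scale it turned in 4 of 9, to -0.43 in gh1-led, -0.30 in somatolactotroph-like, -0.24 in macrophage or microglia-like and -0.10 in erythrocyte-like cells. Mitochondrially encoded genes had a median of 0.04 (percentile 4.66), and within classes they lay below the central 95% of matched lists in 4 of 9: folliculostellate or progenitor-like (-0.45, percentile 0.320), macrophage or microglia-like (-0.47, percentile 0.485), corticotroph-like (-0.24) and lhb-led cells (-0.12). Red blood cell genes had a median of -1.34 (percentile 0), with hbba2 at -2.09, beside the lower erythrocyte-like share; with the same class weights that median turned to 0.55. Cell cycle genes had a median of -0.62 (percentile 0.240), with top2a at -3.23 and mki67 at -2.78 (-1.78 and -1.70 with the same class weights). Within classes that median was 0.64 in lhb-led cells (percentile 99.98; 10 of 12 above the median gene; 0.47 on the CPM scale) and -0.53 in macrophage or microglia-like cells (percentile 1.62; 13 of 15 below). Library-wide it was 0.02 with the same class weights. The sums with those weights left out cluster 23, which cell cycle genes lead, since it had 26 WT cells and 1 amh knockout cell. Whether the cell cycle values would keep their place with that cluster included is not shown.

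Library-wide, the medians of the remaining lists lay between -0.18 and 0.37. Pituitary transcription factors and receptors had a median of -0.18 (percentile 1.53, 22 of 38 below), with the progesterone receptor gene pgr at -1.36. Within classes the median of that list lay below the central 95% of matched lists in 0 of 9 and above it in 1. It was below 0 in 4 classes and above 0 in 5. Hormone processing and secretion genes stood at -0.13 (percentile 0.720; 15 of 23 below), with the prohormone convertase genes pcsk1 at -1.70 and pcsk2 at -1.84. Glucocorticoid-responsive genes were at -0.09 (percentile 1.50), with zbtb16a at -1.39, and the per-cell mean turned that median to 0.21. Antigen presentation and macrophage genes were at -0.04 (percentile 7.38), beside a lower macrophage or microglia-like share. Within classes they were at 1.71 in corticotroph-like and 0.98 in gh1-led cells (percentile 98.9; 6 of 6 above the median gene; -0.35 on the CPM scale), and at -0.87 in somatolactotroph-like cells (percentile 1.34; 4 of 5 below). Medians within the central 95% of matched lists were 0.37 for interferon response genes (percentile 92.3), with isg15 at 1.96 and rsad2 at 1.80, and 0.33 for endoplasmic reticulum stress and protein folding genes (percentile 35.5). They were 0.33 for GABA and melatonin signalling genes (percentile 87.8), with the melatonin receptor gene mtnr1bb at -2.92, but within classes the median was -1.55 in prl-led (percentile 0.0200; 4 genes) and -1.67 in folliculostellate or progenitor-like cells (percentile 0.515; 3 genes). They were 0.09 for activin, inhibin and follistatin genes (percentile 78.3), with fsta, an activin-binding protein gene, at -3.29 on 59 against 3 UMIs (-0.55 with the same class weights), and 0.03 for cholesterol synthesis genes (percentile 61.9). Other within-class medians below the central 95% of matched lists were those of glucocorticoid-responsive genes in erythrocyte-like (-1.04), folliculostellate or progenitor-like (-0.46) and gh1-led cells (-0.29), of cholesterol synthesis (-0.55) and hormone processing and secretion genes (-0.31) in corticotroph-like cells, and of endoplasmic reticulum stress genes in lhb-led cells (-0.04). In macrophage or microglia-like cells the endoplasmic reticulum stress median was above that range (0.43).

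**Figure D3:**
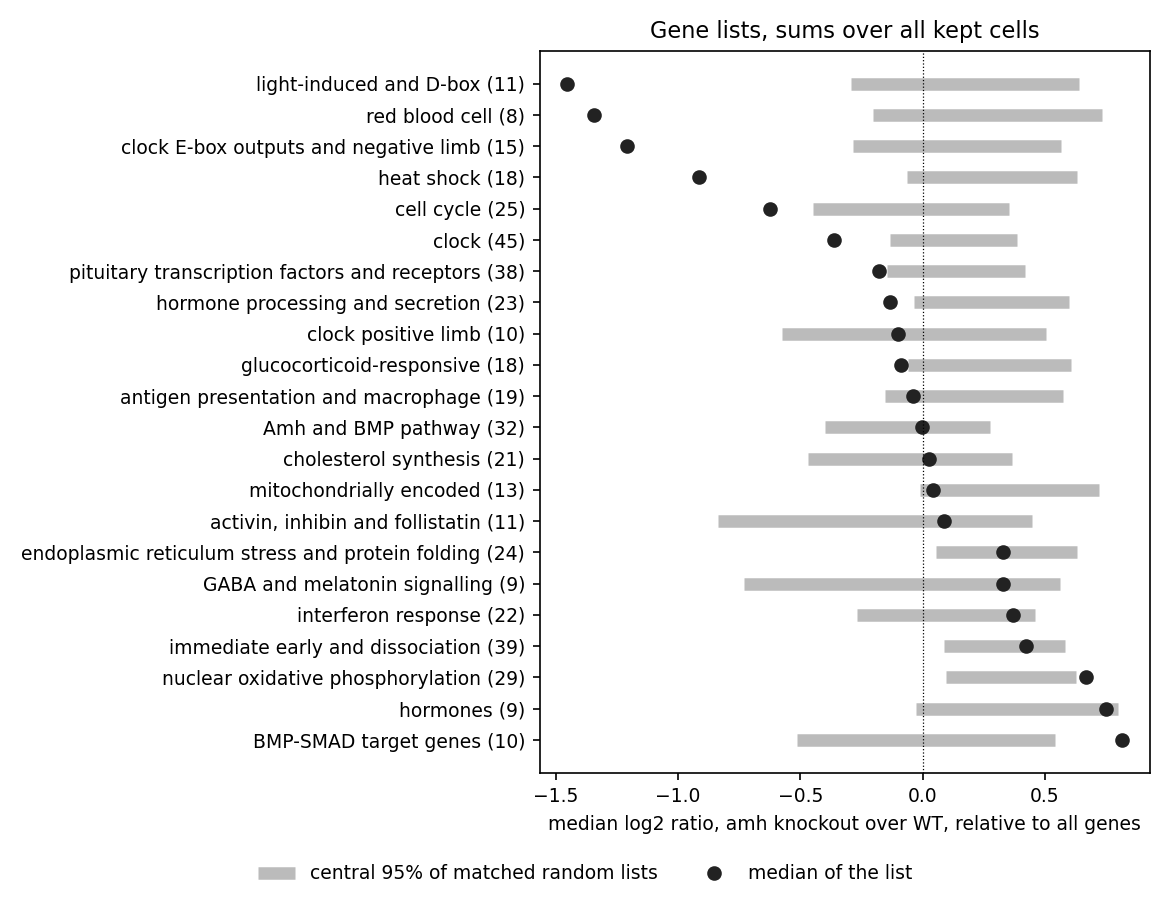
Median log2 ratio (amh knockout over WT) of each gene list relative to all genes, from UMI sums over all kept cells; points are list medians, grey bars the central 95% of 10000 random lists matched on expression, and numbers in brackets are measured members. The light-induced and D-box list lies lowest at -1.45 and the BMP-SMAD target list highest at 0.81; points between 0 and 0.83 lie below 0 on the CPM scale.

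The highest library-wide ratios were for igic1s1, an immunoglobulin gene (8.56; 12 against 2703 UMIs), esm1 (7.93, 7.73 to 8.14; 202 against 28280 UMIs), abcc2 (7.02), cart3 (6.23), the angiotensinogen gene agt (6.19), the oxytocin-family hormone gene oxt (5.44, 4.88 to 6.12; 24 against 611 UMIs) and the muscle filament gene desma (4.78). The esm1 and cart3 UMIs came mainly from gh1-led cells, whose clusters 9 and 19 they help to define. The lowest were CCKBR, a cholecystokinin receptor gene (-5.37, -6.79 to -4.42; 540 against 7 UMIs), alpl (-4.73), SPATA1 (-4.50), the fibroblast growth factor gene fgf8a (-4.04), the neurofilament gene nefma (-3.99), apoa1a (-3.75), the Clock-interacting gene cipca (-3.61) and the transferrin receptor gene tfr1a (-3.56). With the same class weights several of these values came closer to 0: CCKBR was at -1.51, alpl at -1.16, SPATA1 at -0.49, fgf8a at -0.98, apoa1a at -0.85, tfr1a at -2.05 and cipca at -2.54, while nefma was at -3.80. The highest genes named stayed between 4.30 (desma) and 7.59 (igic1s1). Of the lowest, apoa1a was among the 10 leading genes of the fshb-led clusters. The 12 highest and 12 lowest also held 5 and 4 loci with clone names.

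Within classes, several of the most extreme genes recurred. The interferon-induced gene isg15 was at 4.04 (3.61 to 4.53) in lhb-led cells and 3.31 (2.69 to 4.05) in corticotroph-like cells, whose antigen presentation and macrophage genes were higher too. The surface glycoprotein gene thy1 was at 3.08 in lhb-led cells, where it also leads cluster 4, and at 3.30 in folliculostellate or progenitor-like and 1.99 in prl-led cells. The neuropeptide gene galn was at 4.71 (4.16 to 5.38) in prl-led cells, beside the cell cycle inhibitor gene cdkn1a at 4.34, and at 4.62 in folliculostellate or progenitor-like cells on 3 against 141 UMIs. The photolyase gene cry5 was among the lowest in lhb-led (-4.20) and corticotroph-like cells (-3.22), and per3 in folliculostellate or progenitor-like, prl-led and somatolactotroph-like cells. In thyrotroph-like cells the chaperone genes hsp70.1 (-3.12), hsp70.2 (-2.95), hsp90aa1.2 (-2.93) and hsp70l (-2.75) were among the 6 lowest. In macrophage or microglia-like cells cd40 (-4.07) and cxcl19 (-3.86, -4.76 to -3.17) were among the lowest. There, cart3 and esm1, which lead a gh1-led cluster, were among the highest beside the higher gh1 RNA, and whether endocrine cells were joined to these cells was not tested. In erythrocyte-like cells the metallothionein gene mt2 was the highest, at 4.66 on 23 against 77 UMIs.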

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

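The tests of the explanations in this part, with their bounds, were chosen after the result was seen; the E-box and heat shock medians, also with the same class weights, were planned. The nuclear receptor gene rorcb, a member of the clock list, differed in direction between cell classes. Its relative log2 ratio was 1.98 (1.48 to 2.54; 40 against 143 UMIs) in gh1-led cells and -2.0 (-2.62 to -1.46; 164 against 31 UMIs) in prl-led cells. With 1 library per group the difference between the classes was not tested.

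The first pattern weighed is the lower clock and light-regulated genes in the amh knockout library. A loss of weakly expressed genes is argued against by the E-box median of -1.21, which lies below -0.29, the lower end of lists matched on expression. A different makeup of cell classes is argued against as the whole cause by the median of -1.02 with the same class weights. The bound of -0.29 came from sums without these weights. The weights hold the classes alike, not the clusters within a class, which differed between the libraries in lhb-led and corticotroph-like cells. A different makeup within classes therefore stays open. Sampling at another time of day or light phase may give the same values as a genotype effect on the clock: the E-box median was below 0 in 9 of 9 classes, which both predict. The labels give no sampling time and there was 1 library per genotype, so these cannot be told apart, and an effect of amh stays open and untested.

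The second pattern is the small number of fshb-led gonadotroph-like cells in the amh knockout library. A lower level of fshb alone in cells that otherwise stayed as they were predicts no shift in their other leading genes. Such genes were taken from the fshb-led cluster of the WT library clustered alone, hormones left out. Of these, 9 of 9 lay below the median gene, with a median of -2.06 (lower end of matched lists -0.27). They were picked for high values in WT counts that also form the ratio, and leading genes of other WT clusters were not compared. The values therefore do not decide this explanation. Cells that lost fshb with other leading genes and were counted as lhb-led may account for a part, since the classes were named by fshb and lhb; fshb-led and lhb-led cells together had a ratio of shares of 0.721 (0.657 to 0.790), and cluster 4 of the lhb-led class held 11 WT and 624 amh knockout cells. Uneven dissection, dissociation or reproductive stage of the fish might also change shares: 9 of 11 other classes had a ratio of shares whose interval did not include 1. Shares are parts of a whole, so fewer fshb-led and erythrocyte-like cells by themselves raise the other shares. That count is therefore not independent of the pattern. With 1 library per genotype these explanations and a loss of the cells with the genotype cannot be told apart.

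The third pattern is the lower heat shock genes in the amh knockout library. A different makeup of cell classes is argued against as the whole cause by a heat shock median of -0.92 with the same class weights. A different makeup of clusters within a class was not tested by that value. A general gap in dissociation stress stays open, since the immediate early medians of the classes went both ways: 4 of 9 lay above the range of their matched lists and 2 of 9 below it. Temperature or handling of the suspension may have differed, with heat shock medians below 0 in 9 of 9 classes, which a genotype effect predicts too. With 1 library per genotype these cannot be told apart.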

How the results depend on the processing

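Removing the top 5% of cells by UMIs, scanpy's own graph and leaving out erythrocyte-like cells were chosen after seeing the data; the other alternatives were planned. Of the list medians, 235 alternative values stayed within the interval or range of the value reported, 3 moved and 4 reversed; within classes 220 stayed and 2 moved. Library-wide, these counts do not tell whether a median kept its place outside the range of its matched lists. The E-box and light-induced medians kept their sign under every alternative run, library-wide and within classes. Doublets kept is identical to the reported setting, since none were called. Scaling alternatives shift all genes alike, so they cannot move a value relative to the median gene. The counts of values that stayed include these settings. For single genes they also include list medians without members at or under 3 UMIs, a setting that cannot move a gene. When each library was clustered alone, melanotroph-like and prl-led cells gave no amh knockout value, and folliculostellate or progenitor-like cells no value within the class. Depth limits amh, with 13 and 8 UMIs. No paired analysis was possible because each group holds 1 library.

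Relative log2 ratios of single genes were followed for per2, per3, arntl1a, nfil3-5, fshb, gh1 and id1 only. Of these values 57 stayed, 19 moved with no change of direction and 1 reversed. Among those that moved were gh1 and id1, to 1.40 and 1.04 class-standardised, and per3, to -2.02 with the mean of per-cell CPM. Of the ratios of thinned shares 17 stayed and 7 moved with no change of direction, per2 from 0.208 to 0.364 and tefa from 0.260 to 0.463 unthinned. Of the ratios of shares 103 stayed, 22 moved and 4 reversed, and the cause was not tested except where stated. Under the stricter cell filter it was 1.12 for corticotroph-like, 1.62 for folliculostellate or progenitor-like, 1.2 for gh1-led and 1.14 for lhb-led cells, and it reversed to 3.79 for erythrocyte-like cells. When each library was clustered alone it was 1.01 for corticotroph-like, 4.97 for folliculostellate or progenitor-like and 0.390 for fshb-led cells, and it reversed to 3.33 for erythrocyte-like and 1.04 for macrophage or microglia-like cells; under both settings the erythrocyte-like name also went to a cluster of mostly amh knockout cells with gh1 and pomca RNA. In the amh knockout library clustered alone, 120 cells led by soul5 entered the fshb-led class. With classes from the leading hormone it was 2.05 for gh1-led, 2.00 for somatolactotroph-like and 1.25 for thyrotroph-like cells, and reversed to 0.784 for lhb-led cells. At resolution 0.5 it was 1.23 for corticotroph-like and at resolution 2 it was 0.541 for macrophage or microglia-like cells. With all barcodes it was 0.328 for erythrocyte-like and 0.221 for melanotroph-like cells, and without hormone genes in the clustering 0.337 for melanotroph-like and 1.34 for prl-led cells. Without the top 5% of cells it was 1.31 for gh1-led and 1.17 for lhb-led cells, with scanpy's own graph 1.1 for lhb-led cells, and without erythrocyte-like cells, through the smaller denominator, 1.22 for corticotroph-like, 1.33 for gh1-led and 1.23 for lhb-led cells.

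The median log2 ratio of all genes, -0.83, was -0.45 on CPM without hormones, 0.00 with median-of-ratios scaling by construction, -0.47 as a mean of per-cell CPM, -0.62 class-standardised and -0.59 without the top 5% of cells. The glucocorticoid-responsive median reversed to 0.21 with the mean of per-cell CPM, and the cell cycle median to 0.02 class-standardised. The class-standardised sums left out cluster 23, which cell cycle genes lead. Red blood cell genes reversed to 0.55 class-standardised and 0.12 without erythrocyte-like cells, and fshb to 0.37 class-standardised; these settings by construction take out the class shares, and the fshb-led class is named by fshb. Within classes, the E-box median in erythrocyte-like cells was -2.19 when each library was clustered alone, and the light-induced median in somatolactotroph-like cells was -1.0 with classes from the leading hormone.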

Other observations

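Cluster 14, led by soul5, hebp2 and prdx1 and left unnamed, had 196 WT and 114 amh knockout cells and some of the lowest clock and chaperone values. In it per2 had a relative log2 ratio of -4.44 (-4.97 to -3.98; 1746 against 36 UMIs), per3 -3.75 (-4.34 to -3.25), cry5 -4.45 and tefa -3.46. The heat shock median there was -3.09 and all 16 measured heat shock genes lay below the median gene, with hsp90aa1.2 at -3.83 (-4.02 to -3.65; 7987 against 253 UMIs). The immediate early median in the same cells was 0.41.

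In somatolactotroph-like cells the extracellular matrix gene tgfbi was at 4.40 (3.70 to 5.28; 16 against 176 UMIs), and the transcription factor gene zbtb16a at -2.62. In thyrotroph-like cells nppal was at 4.61 and in corticotroph-like cells at 3.17; it is the first leading gene of the prl-led cluster. In folliculostellate or progenitor-like cells the myocilin gene myoc was at -2.98 (-3.61 to -2.43) and adm2a, an adrenomedullin-family gene, at -2.85.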
